A study of Mus musculus with 30 samples.

How the data were processed

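Chromatin accessibility was measured by ATAC-seq or omniATAC-seq in 30 samples of mouse T cells, in 15 groups of 2 libraries each. Groups were taken from the sample titles: wild-type (WT) Treg, BATF knockout (BATFKO) Treg, WT conventional T cells (Tconv), WT effector Treg (eTreg), central Treg (cTreg), effector T cells (Teff) and naive T cells (Tnaive), Foxp3KO Treg and Foxp3R397W Treg each with a WT control pair, and Treg lacking both Foxp3 and BATF (DKO) that received mock, Foxp3, BATF or both retroviruses. Titles name both libraries of a group only by number, and no label says that they came from separate animals.

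The authors deposited 2 tables of normalized peak scores, a signal that is never negative: one of 68597 peaks in 22 libraries and one of 69316 peaks in 26 libraries. The submitters' processing notes name the build mm10 and the tools Bowtie2 2.4.1, MACS2 2.2.7.1, DiffBind 3.0.15 and 3.4.11, and edgeR 3.36.0 and 3.38.4. Their roles and settings are not given in the sources used here. Most peaks were 401 bp wide, and 4 peaks with a negative start were kept. Within a library each score was a whole number of reads divided by 1 factor: 100% of the values were whole to within 0.02 reads. The recovered reads in peaks ranged from 3716499 to 25462278 per library in the 26-library table and from 3713691 to 28958694 in the 22-library table. The ATAC and omniATAC protocols differ in lysis, transposase and amplification. Protocols were read from the titles, and the libraries on both sides of each contrast shared a protocol under the names of either table. Libraries that the tables name differently are ATAC under one name and omniATAC under the other, so which protocol they had is not settled.

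The tables share 18 libraries, of which 6 carry the same name in both and 12 carry different names. Libraries were matched on the 4478 peaks with identical coordinates. Names were used as each table gives them, and tables were fitted separately. The 26-library table was used for every comparison it names. Only the 22-library table has columns named Foxp3KO, so that contrast and its interaction come from there. This choice, and the reading of the columns named as Foxp3 WT Treg as the control pair of Foxp3R397W, were made after seeing the tables. Of the 69316 peaks of the larger table, 66144 overlap a peak of the other by at least 1 bp, and 65934 by at least 0.5 of both peaks.

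Each contrast was tested with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend and robust options) in R 4.3.3 on log2(score + 1), with all groups of a table in one fit. Residual degrees of freedom were 13 in the 26-library table and 11 in the other. Peaks with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. A fold change on this scale understates the change of peaks with low scores. There were 11 contrasts of 2 groups and 3 interactions, all on the scaling as deposited and with no replicate block. In simulated data, the reads of every library were drawn around the same mean per peak. They kept the scaling and dispersions of the real data but no group differences. Among peaks above the median mean score, 100 were then changed 2-fold and 100 changed 4-fold in a single group. The test recovered 56 to 62 of the former and 99 to 100 of the latter, with 4 to 17 false calls among 69316 peaks.

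Peaks were assigned to the nearest protein-coding gene within 100 kb of its body, using the RefSeq annotation of the same build and bedtools 2.31.1. The annotation table gave no strand, so gene bodies replaced the transcription start sites that had been planned. Exons, introns and untranslated regions were not separated. The genes named in the text were picked by a fixed rule. Per contrast it took the 10 peaks with the largest positive and the 10 with the largest negative change among called peaks with an average score above the table median and no overlap between the groups, 1 peak per gene. It also took the 4 genes of each list with the smallest adjusted p, and always a fixed set that includes Foxp3, Batf, Irf4, Ctla4, Il2ra, Ikzf2, Icos, Prdm1, Il10, Tcf7 and Ccr7. Some genes picked by this rule are not reported here. For interactions it took the 5 peaks per direction with the smallest p.

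There were 11 gene lists with 136 genes: Treg identity, effector Treg, naive and central T cell, effector cytokine, helper lineage transcription factor, TCR-induced transcription factor, B cell marker, CD8 and NK cell marker, myeloid marker, erythroid marker and housekeeping. Lists were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 11 lists within a contrast. Of 132 list tests in the 12 contrasts and interactions of the 26-library table, 50 passed at the preset correlation and 25 with an estimated correlation. Sets of peaks called in one contrast were tested with camera in contrasts that share no library with it. There were 35 such tests, and their p-values were adjusted over all 35. Only the sets of peaks higher or lower in eTreg had been planned, and the other sets were added after the counts were seen. Overlaps of called peaks were tested with Fisher's exact test (two-sided), with peaks as units although peaks are not independent replicates.

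The contrasts, the tests, the lists, the rule for named genes and most alternatives were fixed before the data were examined. Those alternatives were other pseudocounts (0.5 and 5), a filter on low scores, TMM and quantile scaling, a test against a 1.5-fold change (treat), plain eBayes, only the groups compared or only 1 protocol in the fit, a replicate block, all 4 omniATAC WT Treg libraries as control, and leaving out each library in turn. After seeing the data, edgeR 4.0.16 (glmQLFit and glmQLFTest) on the recovered reads, the names of the 22-library table, the reads of that table under the other table's names, a minimum of 10 reads, and a replicate block for Foxp3R397W, the Foxp3KO contrast and its interaction (by the column numbers of the 26-library table) and in the fit of only the DKO groups were added. Same-numbered DKO libraries deviated together from their group means (r from 0.15 to 0.21 in all 6 pairs of groups), so the numbers of the titles were taken to pair them in the replicate block, although no label says what a number shares. The DKO changes and counts of the main fit do not use this pairing. Motifs were not analysed here, since no genome sequence was used.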

Results

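The series addressed how Foxp3 and BATF shape chromatin accessibility in effector Treg. Mouse T cells from lymph nodes and spleen gave 30 samples in 15 groups, with 2 libraries per group. Central Treg were sorted by surface markers that include CCR7 (high) and CD44 (low), and DKO Treg were sorted after transduction with mock, Foxp3, BATF or both retroviruses. Reads in peaks ranged from 3716499 to 25462278 per library over the 69316 peaks of the 26-library table. At this depth the median SE of a log2 change between a pair of groups was 0.34. Values are the mean ± SD of the normalized score (SD, n = 2), and changes are log2 differences with their SE and Benjamini-Hochberg adjusted p from limma. In every peak named as higher or lower between a pair of groups, both libraries of the higher group lay above both of the lower group. The p-values measure only the spread between these samples, which may be technical, since no label says that they came from separate animals.

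The targeted genes were examined first. A peak at Batf (mm10 chromosome 12, 85686411 to 85686811) held 523 reads in WT Treg (289 ± 33) and 0 reads in both BATFKO libraries, at least 106-fold lower with a floor of 3 reads per library. In DKO Treg the same peak held 2 reads with mock virus, 8 with Foxp3, 2 with BATF and 0 with both. A peak at Foxp3 (mm10 chromosome X, 7583922 to 7584322), the lineage factor of Treg, scored 379 ± 19 in WT Treg, 403 ± 46 in cTreg and 372 ± 13 in eTreg. It scored 9.27 ± 6.2 in Tconv and 5.17 ± 5.5 in Tnaive. Foxp3R397W Treg (329 ± 14) and their WT control (401 ± 23) both carried this peak, as did DKO Treg with mock virus (892 ± 320).

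Library names differed between the deposited tables. The 22-library and 26-library tables shared 18 libraries, whose reads were equal at 98% to 100% of identical peaks, against 0.938% to 3.35% for the next best match. Of these, 12 carried another name in each table. Libraries that the 26-library table calls eTreg, cTreg, Tnaive, Teff, Foxp3 WT Treg and Foxp3R397W are called WT Treg 3 and 4, Foxp3R397W, WT Treg 5 and 6, Foxp3KO, cTreg and eTreg in the other. The name Foxp3 WT Treg does not tell which mutant the pair controls, and it was read here as the Foxp3R397W control. A Treg index, the mean log2 score at peaks at least 2-fold higher in WT Treg than in Tconv minus that at peaks at least 2-fold lower, compared them. In the 26-library table it was 1.33 and 1.06 in WT Treg, −2.54 and −2.60 in Tconv, 2.44 and 2.44 in eTreg, −0.24 and −0.33 in cTreg, −3.25 and −3.21 in Tnaive and −0.01 and −0.14 in Teff. In the 22-library table the libraries named WT Treg 5 and 6 stood at −2.93 and −2.90, below Tconv (−2.28 and −2.31), while those named Tnaive stood at 1.39 and 1.48. The names of the 26-library table were therefore used for every comparison it allows.

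**Figure D1:**
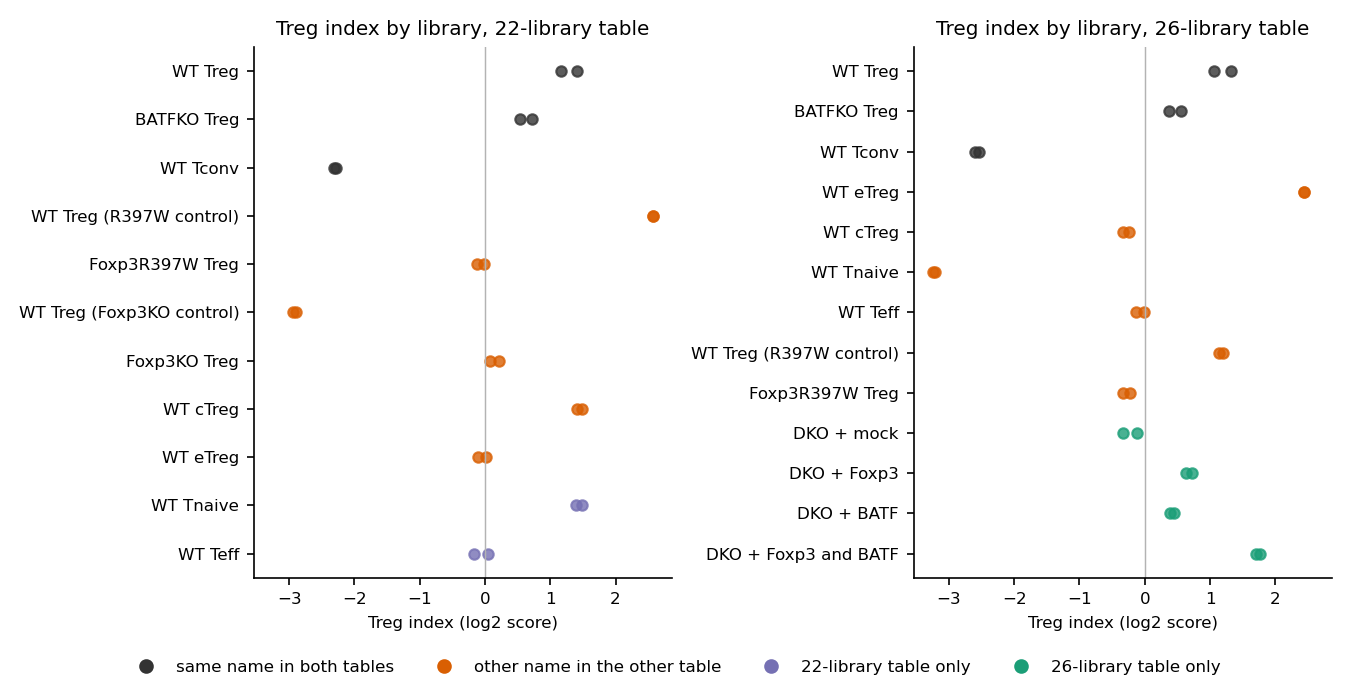
Treg index (log2) of each library in the 26-library and 22-library tables, by the group name that each table gives; points are libraries. Libraries named Tnaive stand at −3.25 and −3.21 in the former and at 1.39 and 1.48 in the latter.

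WT Treg were compared with Tconv to ask which sites set Treg apart. The Foxp3 peak rose from 9.27 ± 6.2 in Tconv to 379 ± 19 in WT Treg (log2 5.35, SE 0.50, adjusted p = 7.7e-07). A peak at Lrrc32, which encodes the receptor GARP that presents latent TGF-beta, rose from 7.49 ± 0.95 to 238 ± 36 (4.81, SE 0.31, 1.9e-11). Peaks at Ctla4, an inhibitory receptor (82.6 ± 25 to 602 ± 58), and at Ikzf2, which encodes Helios (97.9 ± 16 to 515 ± 55), rose by 2.88 and 2.39. A peak at Il2, the T cell growth factor that Treg make little of, fell from 482 ± 120 to 153 ± 4.1 (−1.63, SE 0.21, 9.5e-07). A peak at Lef1, a transcription factor of naive T cells, fell from 173 ± 41 to 35.2 ± 6.5 (−2.26).

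Of 211 peaks at Treg identity genes, 98 were higher and 10 lower (111 and 14 adjusted over the list alone, list adjusted p = 6e-14). Effector Treg genes had 72 higher and 16 lower of 236 peaks (79 and 17 adjusted over the list alone; 6e-07), among them peaks at Irf4 (11.7 ± 2.7 to 80.3 ± 4.7), Il10 (17.3 ± 1.3 to 94.1 ± 10) and Pdcd1 (15.6 ± 3.6 to 133 ± 18). CD8 and NK cell markers had 1 higher and 10 lower (1e-04). Both other lists that passed lost the call with an estimated correlation: B cell markers with 6 higher (adjusted p = 0.012, and 0.078 with an estimated correlation) and myeloid markers with 3 higher and 11 lower (0.026 and 0.059). Over all peaks, 7012 were higher and 6878 lower in WT Treg. The 22-library table, which names these libraries alike, gave 14827 higher and 5852 lower, so the balance of directions depends on the table. Against a 1.5-fold change 4811 peaks passed, and without WT Treg 1 the count was 8332.

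Effector and central Treg were compared to describe the effector state itself. A peak near Il10, which encodes a suppressive cytokine (chromosome 1, 131010535 to 131010935), rose from 10.5 ± 2.3 in cTreg to 236 ± 1.1 in eTreg (4.38, SE 0.25, adjusted p = 1e-13). A peak at Tigit, an inhibitory receptor, rose from 5.87 ± 0.5 to 298 ± 11 (5.45, SE 0.31, 1.4e-13), and a peak at Klrg1, a receptor of terminally differentiated cells, from 5.31 ± 1.3 to 131 ± 43 (4.36, SE 0.34, 4.8e-11). Peaks at genes of naive cells closed: Lef1 fell from 156 ± 2.7 to 19.8 ± 8.1 (−2.98), Satb1, a chromatin organizer, from 182 ± 25 to 8.56 ± 1.1 (−4.26), and Ccr7, the lymph node homing receptor, from 138 ± 4.8 to 24.9 ± 7.1 (−2.45, SE 0.23, 1.3e-09). Tcf7, which encodes TCF-1, fell by 2.13.

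The naive and central T cell list had 34 peaks higher and 212 lower of 402 (34 and 220 adjusted over the list alone, list adjusted p = 2.1e-14), and the effector Treg list had 111 higher and 23 lower of 236 (118 and 25, 6.9e-08). CCR7 was a sorting marker of cTreg, so Ccr7 is not independent of the gate. Effector cytokines had 32 higher and 6 lower of 74 peaks (37 and 6, 0.00068), including Il4 (6.42 ± 0.28 to 57.5 ± 1.8) and Ifng (21.2 ± 1.1 to 148 ± 11), while Il21 fell from 92.8 ± 11 to 9.64 ± 2. CD8 and NK cell markers had 5 higher and 14 lower (0.0014), with Prf1, which encodes perforin, down from 153 ± 45 to 13.7 ± 2.1. B cell markers had 10 higher and 3 lower (0.032, but adjusted p = 0.12 with an estimated correlation), led by Pax5 (11.5 ± 2.4 to 132 ± 1.9).

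Treg identity genes moved both ways, 41 higher and 49 lower (list adjusted p = 0.74; median −0.10, mean 0.09, test downward). Ctla4 (18.9 ± 3.4 to 197 ± 23) and Ikzf2 (23.3 ± 2.8 to 194 ± 21) each had a peak that rose. Helper lineage transcription factors had 35 higher and 37 lower (0.74; median −0.01, mean 0.11, test downward) and TCR-induced transcription factors 48 higher and 33 lower (0.74; median −0.02, mean 0.14, test upward). Myeloid markers had 9 and 9 (0.74), housekeeping genes 2 and 2 (0.74), and erythroid markers 3 lower of 6 (0.065). Over all peaks 13632 were higher and 12050 lower in eTreg (12715 and 14982 with quantile scaling). Tested against a 1.5-fold change, 13436 passed. Under the names of the 22-library table, which there belong to other libraries, 3864 passed.

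**Figure D2:**
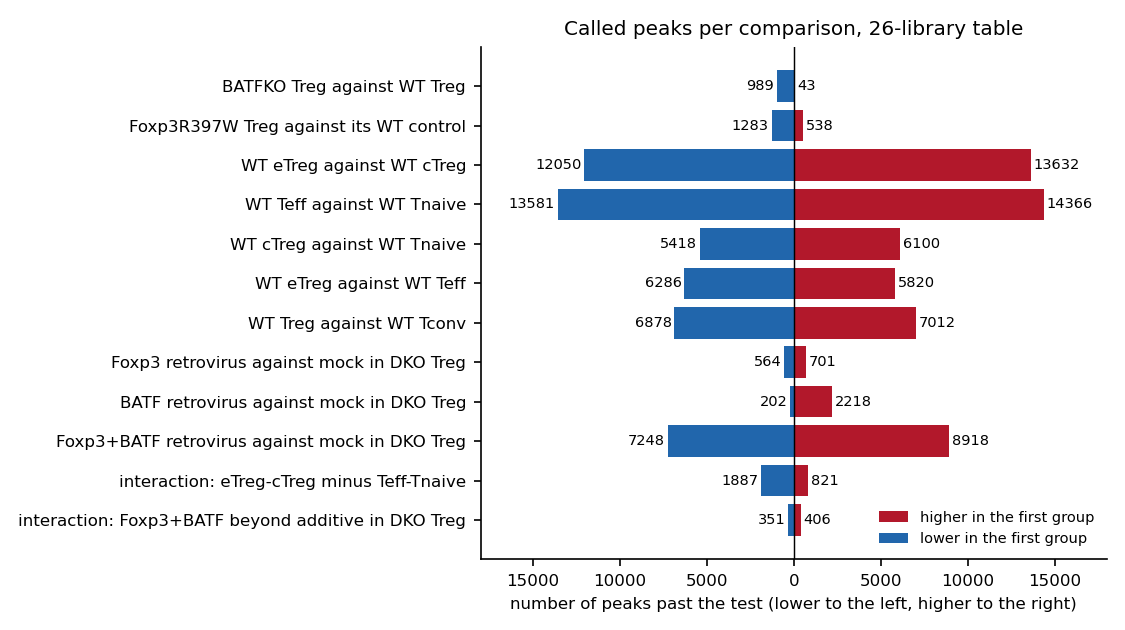
Peaks called higher (above 0) and lower (below 0) per contrast in the 26-library table, of 69316 tested with limma; bars are counts of peaks. Teff against Tnaive (14366 higher and 13581 lower) and eTreg against cTreg (13632 and 12050) have the longest bars, 27947 and 25682 peaks with both directions together.

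Teff were compared with Tnaive as the effector step of conventional T cells. The Il10 peak rose from 3.86 ± 0.039 in Tnaive to 157 ± 24 in Teff (5.01, SE 0.25, adjusted p = 1.7e-15), and a Ctla4 peak from 6.44 ± 1.9 to 135 ± 3.2 (4.22). A peak at Rora, which encodes the nuclear receptor ROR-alpha, rose from 3.21 ± 0.88 to 369 ± 54 (6.47), and a peak at Ifng, the type 1 cytokine, from 8.38 ± 4.6 to 174 ± 9.1 (4.31, SE 0.31, 4e-12). The Klrg1 peak held 0 reads in Tnaive and scored 210 ± 1.6 in Teff, at least 54.5-fold higher. Lef1 fell from 255 ± 4.4 to 23.1 ± 0.59 (−3.41) and Tcf7 from 175 ± 13 to 52 ± 0.28 (−1.73).

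Effector Treg genes had 130 higher and 27 lower peaks (135 and 33 adjusted over the list alone, list adjusted p = 8.7e-11), and effector cytokines 45 and 8 (48 and 9, 2.4e-09). The naive and central list had 39 higher and 224 lower (46 and 238, 3.3e-12, and adjusted p = 0.063 with an estimated correlation), and CD8 and NK cell markers 6 and 18 (0.018, and 0.063 with an estimated correlation). In all, 14366 peaks were higher and 13581 lower in Teff (14266 and 14374 with quantile scaling). Of the 13632 peaks higher in eTreg than cTreg, 9598 (70.4%) were also higher in Teff than Tnaive (odds ratio 25.4, 95% interval 24.2 to 26.7, Fisher's exact test). Across peaks, which are not independent, the changes had r = 0.792 (rho 0.769). Against a 1.5-fold change 14987 peaks passed. Under the names of the 22-library table, which there belong to other libraries, 4158 passed.

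The interaction asked where the effector step differed between Treg and conventional cells. At an Ikzf2 peak (chromosome 1, 69544222 to 69544622) scores were 523 ± 51 in cTreg and 715 ± 17 in eTreg, against 25 ± 7.9 in Tnaive and 544 ± 37 in Teff (difference of changes −3.97, SE 0.32, adjusted p = 4.3e-09). A peak 23416 bp from the body of Cd47, which encodes a signal against phagocytosis, went from 369 ± 3.9 to 577 ± 10 in Treg and from 11.6 ± 3.5 to 523 ± 22 in conventional cells (−4.77, SE 0.32, 1.6e-10), and a peak in Prr5l, which encodes a partner of mTOR complex 2, from 202 ± 8.4 to 204 ± 13 and from 10.9 ± 2.8 to 190 ± 11 (−4.01). A peak at Mynn, a zinc finger gene, rose from 18.2 ± 7 to 149 ± 10 in Treg and scored 367 ± 42 in Tnaive and 107 ± 1.6 in Teff (4.78, SE 0.53, 8.9e-07).

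For this difference, Treg identity genes had 2 peaks higher and 25 lower (7 and 34 adjusted over the list alone, list adjusted p = 0.00019), effector cytokines 1 and 14 (1 and 23, 5.8e-06) and helper lineage transcription factors 15 lower (21; 0.00035). The effector Treg list had 1 and 16 (0.0056, and adjusted p = 0.19 with an estimated correlation). In all, 821 peaks were higher and 1887 lower. Under the names of the 22-library table, which there belong to other libraries, 0 passed with limma (465 at an unadjusted p under 0.05, and 2705 with edgeR under the other names). The count was 745 against a 1.5-fold change, 4217 with pseudocount 5 and 4555 when only the 4 groups were fitted. It was 1347 without Teff 2, 1685 without eTreg 1, 1738 without eTreg 2, 1689 without cTreg 2 and 1692 without Teff 1.

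Central Treg and Tnaive were compared to find what marks Treg before the effector step. The Foxp3 peak (5.17 ± 5.5 to 403 ± 46; 6.39, SE 0.50, adjusted p = 7.2e-08), the Ikzf2 peak (25 ± 7.9 to 523 ± 51; 4.36, SE 0.22, 1.3e-14) and an Lrrc32 peak (3.88 ± 3.7 to 209 ± 4.5; 5.67, SE 0.31, 1.8e-13) rose in cTreg. Peaks at Il2 (628 ± 3.6 to 190 ± 20; −1.72) and Klrd1, which encodes the NK receptor CD94 (350 ± 96 to 47.2 ± 13; −2.86), fell. Treg identity genes had 108 peaks higher and 6 lower (119 and 11 adjusted over the list alone, list adjusted p = 5.8e-27), and effector Treg genes 71 and 14 (76 and 16, 1.1e-07). Helper lineage transcription factors had 34 and 3 (0.004, and adjusted p = 0.052 with an estimated correlation), myeloid markers 1 and 13 (0.004), and CD8 and NK cell markers 2 and 7 (0.004). Further lists passed upward and lost the call with an estimated correlation: B cell markers with 4 higher (0.033, and adjusted p = 0.13), erythroid markers with 2 and 1 (0.046 and 0.089) and TCR-induced transcription factors with 31 and 8 (0.0098 and 0.17). The naive and central list had 35 and 34 (0.92). In all, 6100 peaks were higher and 5418 lower. The 22-library table gives both of these names to other libraries. Against a 1.5-fold change 4497 peaks passed, without cTreg 1 the count was 7582, and 5 passed (886 at an unadjusted p under 0.05) under the names of the 22-library table.

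Effector Treg and Teff were compared to ask what distinguishes both effector populations. The Foxp3 peak (7.83 ± 0.008 to 372 ± 13; 5.40, SE 0.50, adjusted p = 1e-06), an Lrrc32 peak (13 ± 2.4 to 255 ± 8.6; 4.21, SE 0.31, 3.7e-10) and a Ctla4 peak (15.3 ± 3.2 to 197 ± 12; 3.61) were higher in eTreg. So were peaks at Areg, a tissue repair factor (37.6 ± 6.3 to 341 ± 2.9; 3.16), and Ccr8, a chemokine receptor of tissue Treg (72.6 ± 6.6 to 268 ± 8.9; 1.87). Of 5 peaks at Ccr8, 1 was higher and 1 lower in eTreg. Lower in eTreg were Il23r, the IL-23 receptor (498 ± 77 to 42.9 ± 12; −3.52, SE 0.30, 2.3e-09), Il21 (59.6 ± 4.2 to 9.6 ± 3.7; −2.56), Ifng (47.1 ± 8.5 to 10.3 ± 2; −2.09) and Prf1 (129 ± 23 to 13.7 ± 2.1; −3.14).

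Treg identity genes had 79 higher and 7 lower peaks (89 and 10 adjusted over the list alone, list adjusted p = 3.8e-14), effector cytokines 1 and 18 (6 and 21, 5.3e-05), and CD8 and NK cell markers 4 and 12 (5.3e-05). The effector Treg list had 49 and 18 (52 and 20, 0.0042, and adjusted p = 0.14 with an estimated correlation), and B cell markers 4 higher (0.0065, and 0.081 with an estimated correlation). In all, 5820 peaks were higher and 6286 lower in eTreg. The count was 4108 against a 1.5-fold change, 19384 when only both groups were fitted, and 4 (1390 at an unadjusted p under 0.05) under the names of the 22-library table, which there belong to other libraries. It was 6891 without Teff 2, 7859 without Teff 1, 7621 without eTreg 1 and 7540 without eTreg 2.

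BATFKO Treg were compared with WT Treg to ask which sites need BATF. Most called peaks were lower in BATFKO Treg. A peak at Nrp1, which encodes the Treg surface receptor neuropilin 1 (chromosome 8, 128549736 to 128550136), fell from 281 ± 47 to 5.49 ± 2.4 (−5.48, SE 0.26, adjusted p = 1.9e-14), and a peak at Mmp10, a matrix protease gene, from 278 ± 42 to 7.11 ± 0.66 (−5.10, SE 0.37, 2.8e-10). A peak at Maf, which encodes the transcription factor c-Maf, fell from 101 ± 4.2 to 10.1 ± 5.3 (−3.29, SE 0.37, 9.3e-07). The Il10 peak fell from 94.1 ± 10 to 26.4 ± 8.8 (−1.83, SE 0.25, 2.1e-05), a Tigit peak from 104 ± 3.7 to 30 ± 14 (−1.83), and a Ctla4 peak from 602 ± 58 to 196 ± 97 (−1.71, SE 0.27, 0.00023). A peak at Cd86, a costimulatory ligand gene, was higher (60.2 ± 12 to 189 ± 6.3; 1.64). Neither Foxp3 (−0.36, adjusted p = 0.99), Irf4 (−0.39, 0.86), Tcf7 (0.59, 0.38) nor Ccr7 (0.89, 0.18) passed at its peak with the smallest p.

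At effector Treg genes 11 of 236 peaks were lower, in 9 genes (2 higher and 21 lower adjusted over the list alone, list adjusted p = 2.4e-05, and 0.10 with an estimated correlation). Treg identity genes had 9 lower of 211, at 4 genes (10 adjusted over the list alone; 0.02, and adjusted p = 0.13 with an estimated correlation), with Ikzf2 down from 515 ± 55 to 188 ± 31. Among naive and central genes 11 peaks were lower (0.74), including Bach2, a repressor of effector differentiation (74.4 ± 1.6 to 12.6 ± 1.7). B cell markers had 1 lower (0.028, and adjusted p = 0.13 with an estimated correlation), at Pax5 (62 ± 3.9 to 7.51 ± 3.5). In all, 43 peaks were higher and 989 lower; with quantile scaling 504 were higher and 2007 lower, moving the share that was higher from 4.17% to 20.1%. The count of 1032 was 356 against a 1.5-fold change (the Ikzf2 and Cd86 calls were lost), 1600 with pseudocount 5, 1797 with edgeR and 1418 in the 22-library table. It was 347 without WT Treg 1 and 659 without BATFKO 2.

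Foxp3R397W Treg were compared with their WT control to ask what this Foxp3 variant changes. A peak at Ptafr, the receptor of platelet-activating factor, fell from 122 ± 5.6 to 11 ± 3.6 (−3.39, SE 0.34, adjusted p = 1.6e-06), a Klrg1 peak from 66.3 ± 7.7 to 11.8 ± 3.2 (−2.41, SE 0.36, 0.00036), and the Nrp1 peak from 269 ± 1.5 to 72 ± 4 (−1.89, SE 0.26, 0.00012). An Ikzf2 peak fell from 116 ± 29 to 30.6 ± 8.4 (−1.88) and a peak at Nfil3, a transcription factor gene, from 93.2 ± 6 to 30.8 ± 4.2 (−1.57; lost against a 1.5-fold change). Peaks at Nemp2, which encodes a nuclear envelope protein (41.6 ± 9.7 to 210 ± 46; 2.31, SE 0.24, 2.9e-06), and Zmat4 (10.4 ± 0.59 to 53.1 ± 15; 2.21) rose. The peaks with the smallest p at Foxp3 (1.13, adjusted p = 0.21), Irf4 (−0.88, 0.083), Tcf7 (0.65, 0.084) and Ccr7 (0.63, 0.16) did not pass.

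Effector Treg genes had 1 higher and 20 lower peaks, the latter at 9 genes (2 and 39 adjusted over the list alone, list adjusted p = 1e-09). Treg identity genes had 12 lower at 5 genes (18 adjusted over the list alone; 6.4e-08). Lists that fell with them but lost the call with an estimated correlation were B cell markers, with 1 lower (median −0.46; 0.0046, and adjusted p = 0.083), and TCR-induced transcription factors, with 6 lower (0.048 and 0.31). The naive and central list had 13 higher and 4 lower (15 and 5, 6.8e-09, and adjusted p = 0.14 with an estimated correlation), with Satb1 up from 153 ± 21 to 281 ± 23 (lost without Foxp3R397W 1 or control 2). In all, 538 peaks were higher and 1283 lower. Under the names of the 22-library table, which there belong to other libraries, 28328 peaks passed. The count of 1821 was 100 against a 1.5-fold change, 2786 with pseudocount 5, 6571 when only both groups were fitted and 6303 with edgeR. It was 287 without control 1, 470 without control 2, 455 without Foxp3R397W 1 and 495 without Foxp3R397W 2.

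Peaks of the effector step were then followed in both mutants, as planned. The 13632 peaks higher in eTreg had a median change of −0.30 in BATFKO Treg (10 called higher and 925 lower; adjusted p = 1.3e-25) and −0.55 in Foxp3R397W Treg (16 and 1160, 2.5e-48). The 12050 peaks lower in eTreg had medians of 0.14 (1.1e-06) and 0.33 (3.9e-27). These calls held with an estimated correlation. Of the 989 peaks lower in BATFKO Treg, 925 (93.5%) were higher in eTreg than cTreg (odds ratio 63.3, 95% interval 49 to 82.9, Fisher's exact test), as were 1160 (90.4%) of the 1283 peaks lower in Foxp3R397W Treg (42, 34.8 to 51.1). Of the 538 peaks higher in Foxp3R397W Treg, 425 (79.0%) were lower in eTreg (18.5, 15 to 23). BATFKO and Foxp3R397W shared 277 lower peaks, against 18.3 under independence over all peaks (26, 22.3 to 30.4). Both sets lay mostly among eTreg-higher peaks, and within those more shared peaks would be expected under independence.

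**Figure D3:**
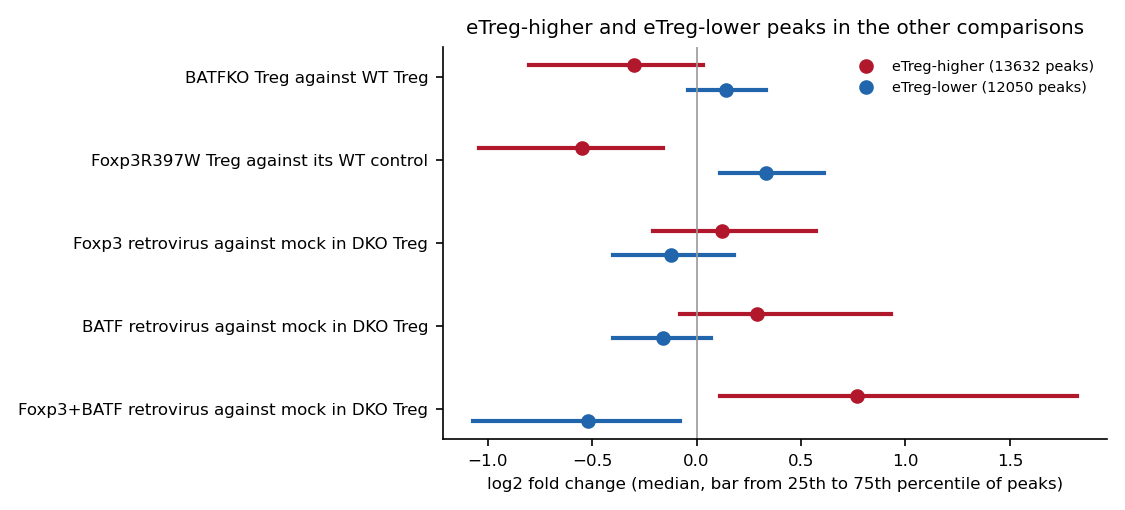
Median log2 change, in the mutant and retrovirus contrasts, of the peaks higher (13632) and lower (12050) in eTreg than cTreg; bars span the 25th to 75th percentile of the peaks. Peaks higher in eTreg lie below 0 in BATFKO and Foxp3R397W Treg and above 0 with BATF or both retroviruses.

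The name Foxp3KO stands in the 22-library table alone. The libraries labelled Foxp3KO scored 8.47 ± 0.45 at the Foxp3 peak (chromosome X, 7583920 to 7584320), those labelled as their WT control 4.54 ± 4.9 and WT Treg 311 ± 39. The 26-library table calls the same libraries Teff and Tnaive. Between them 23412 peaks were higher and 10307 lower of 68597. The median of all peaks was 0.29; quantile scaling shifted it by −0.31 and gave 15365 higher and 15848 lower, and TMM by −0.27 with 17328 and 15679. Peaks higher in eTreg had a median of 1.90 here (10950 called higher of 12746, and 18 lower), and 4 of the peaks lower here were also lower in Foxp3R397W Treg, against 192 under independence (odds ratio 0.0173, 95% interval 0.0047 to 0.0445, Fisher's exact test). The interaction set this change against that between the libraries named Foxp3R397W and their control in the 22-library table, which the 26-library table calls cTreg and eTreg, so it does not use the Foxp3R397W pair of the rest of this text. It gave 23573 higher and 15264 lower peaks (quantile 18461 and 20714, shift −0.37; TMM 20304 and 19919, shift −0.28). Given these names, no account gene by gene is made of this pair. Against a 1.5-fold change 16498 peaks passed between the libraries labelled Foxp3KO and their control. With all 4 omniATAC WT Treg libraries as control, which the 26-library table calls eTreg and Tnaive, 2859 passed.

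Foxp3 was returned to DKO Treg to ask what it opens without BATF. The Nemp2 peak fell from 312 ± 7.7 with mock virus to 90.2 ± 14 with Foxp3 (−1.79, SE 0.24, adjusted p = 0.00016), and a peak at Bpgm, an enzyme gene of red cell glycolysis, from 105 ± 24 to 19.6 ± 4.9 (−2.37, SE 0.30, 7.7e-05). Peaks at Rin2, a Rab5 regulator gene (9.1 ± 0.95 to 46.2 ± 4.6; 2.22, SE 0.28, 7.7e-05), and Tox, a transcription factor gene of stimulated T cells (20.4 ± 4 to 76.4 ± 24; 1.83; lost against a 1.5-fold change), rose. An Ikzf2 peak rose from 57.1 ± 6.3 to 108 ± 20 and an Il2 peak fell from 327 ± 33 to 190 ± 44 (0.90 and −0.80, adjusted p = 0.027 and 0.039; each lost under several settings). At Ctla4 (0.52, adjusted p = 0.42), Il10 (−0.83, 0.31), Tcf7 (−0.57, 0.25) and Ccr7 (−0.71, 0.25) the peak with the smallest p did not pass.

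Few list members passed: effector Treg 4 higher and 1 lower (list adjusted p = 0.51), Treg identity 4 and 2 (0.29), TCR-induced transcription factors 6 higher (10 and 2 adjusted over the list alone; 0.29), and naive and central genes 3 higher (0.51). Effector cytokines had 1 lower (2 adjusted over the list alone; 0.011, and adjusted p = 0.24 with an estimated correlation). B cell markers, with 5 peaks higher adjusted over the list alone, had a median of 0.48 (0.00019, and adjusted p = 0.056 with a replicate block and an estimated correlation). In all, 701 peaks were higher and 564 lower. The count of 1265 was 324 with quantile scaling, 62 against a 1.5-fold change, 334 when only both groups were fitted and 547 within 1 protocol. It was 321 without mock 2, 564 without Foxp3 2 and 1882 without Foxp3 1.

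When BATF alone was returned to DKO Treg, most called peaks were higher. The Mmp10 peak rose from 5.53 ± 1.9 to 282 ± 9.3 (5.47, SE 0.37, adjusted p = 7.1e-11), the Maf peak from 8.17 ± 1.9 to 164 ± 14 (4.19, SE 0.37, 5.1e-09), the Ikzf2 peak lower in BATFKO Treg from 69.5 ± 1.6 to 524 ± 100 (2.88, SE 0.22, 7.3e-10) and the Ctla4 peak from 276 ± 48 to 1350 ± 430 (2.26). The Il10 peak rose from 80.5 ± 13 to 320 ± 1.2 (1.99, SE 0.25, 2.4e-06), a peak at Prdm1, which encodes Blimp-1, from 8.65 ± 1.2 to 35.1 ± 12 (1.87), and a peak at Il17a, a cytokine of type 17 cells, from 23 ± 4.8 to 171 ± 0.75 (2.86). The Bach2 peak named for BATFKO Treg rose from 19.9 ± 3.2 to 142 ± 19. Neither Tcf7 (−0.65, adjusted p = 0.32), Ccr7 (−0.61, 0.49) nor Foxp3 (0.32, 0.77) passed at its peak with the smallest p.

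The effector Treg list had 17 higher peaks at 8 genes (26 adjusted over the list alone, list adjusted p = 0.00013, and 0.16 with an estimated correlation). Treg identity genes had 16 higher at 4 genes (18 and 1 lower adjusted over the list alone; 0.10), effector cytokines 8 higher (9 and 2, 0.062), and naive and central genes 13 higher and 1 lower (0.082; the test, the median of −0.14 and the mean of −0.07 were all negative). In all, 2218 peaks were higher and 202 lower. The count against a 1.5-fold change was 943, and it was 1460 without BATF 2 and 1463 without mock 2.

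DKO Treg with both retroviruses were compared with those given mock virus. The Nrp1 peak rose from 36.5 ± 0.92 to 739 ± 180 (4.28, SE 0.26, adjusted p = 1.5e-12), a Prdm1 peak from 8.65 ± 1.2 to 95.5 ± 3.3 (3.33, SE 0.31, 3.4e-09), the Il10 peak from 80.5 ± 13 to 459 ± 92 (2.49, SE 0.25, 8.6e-09) and a peak at Il1rl1, the IL-33 receptor, from 3.54 ± 0.53 to 161 ± 45 (5.14). Not all peaks of these genes rose: Prdm1 had 6 higher and 4 lower of 20, and Nrp1 12 higher and 5 lower of 38. Tcf7 fell from 230 ± 15 to 44.5 ± 14 (−2.37, SE 0.24, 9.3e-09), Satb1 from 317 ± 59 to 58.9 ± 1.9 (−2.40) and Bcl2, a survival gene, from 249 ± 3.2 to 43.1 ± 16 (−2.55). Il23r (118 ± 5.9 to 11.6 ± 0.096; −3.24), Il2 (327 ± 33 to 123 ± 25; −1.42) and Il21 (415 ± 2.1 to 148 ± 42; −1.51) fell, while Il17a rose from 23 ± 4.8 to 249 ± 43.

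Effector Treg genes had 79 higher and 15 lower peaks (89 and 19 adjusted over the list alone, list adjusted p = 3.9e-08), and naive and central genes 31 and 163 (37 and 184, 1.3e-10, and adjusted p = 0.088 with an estimated correlation). Treg identity genes had 44 and 18 (47 and 19, 0.045, and adjusted p = 0.17 with an estimated correlation), B cell markers 9 higher (11 adjusted over the list alone; 0.00015), myeloid markers 9 and 3 (0.014), and effector cytokines 8 and 16 (0.11). TCR-induced transcription factors had 32 and 23 (0.93; median −0.10, mean 0.17, test upward) and housekeeping genes 2 higher (0.67; median −0.15, mean 0.05, test downward). In all, 8918 peaks were higher and 7248 lower, while quantile scaling gave 6646 and 7439 and TMM 8317 and 8733. Against a 1.5-fold change 6768 passed, and without mock 2 the count was 10773.

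**Figure D4:**
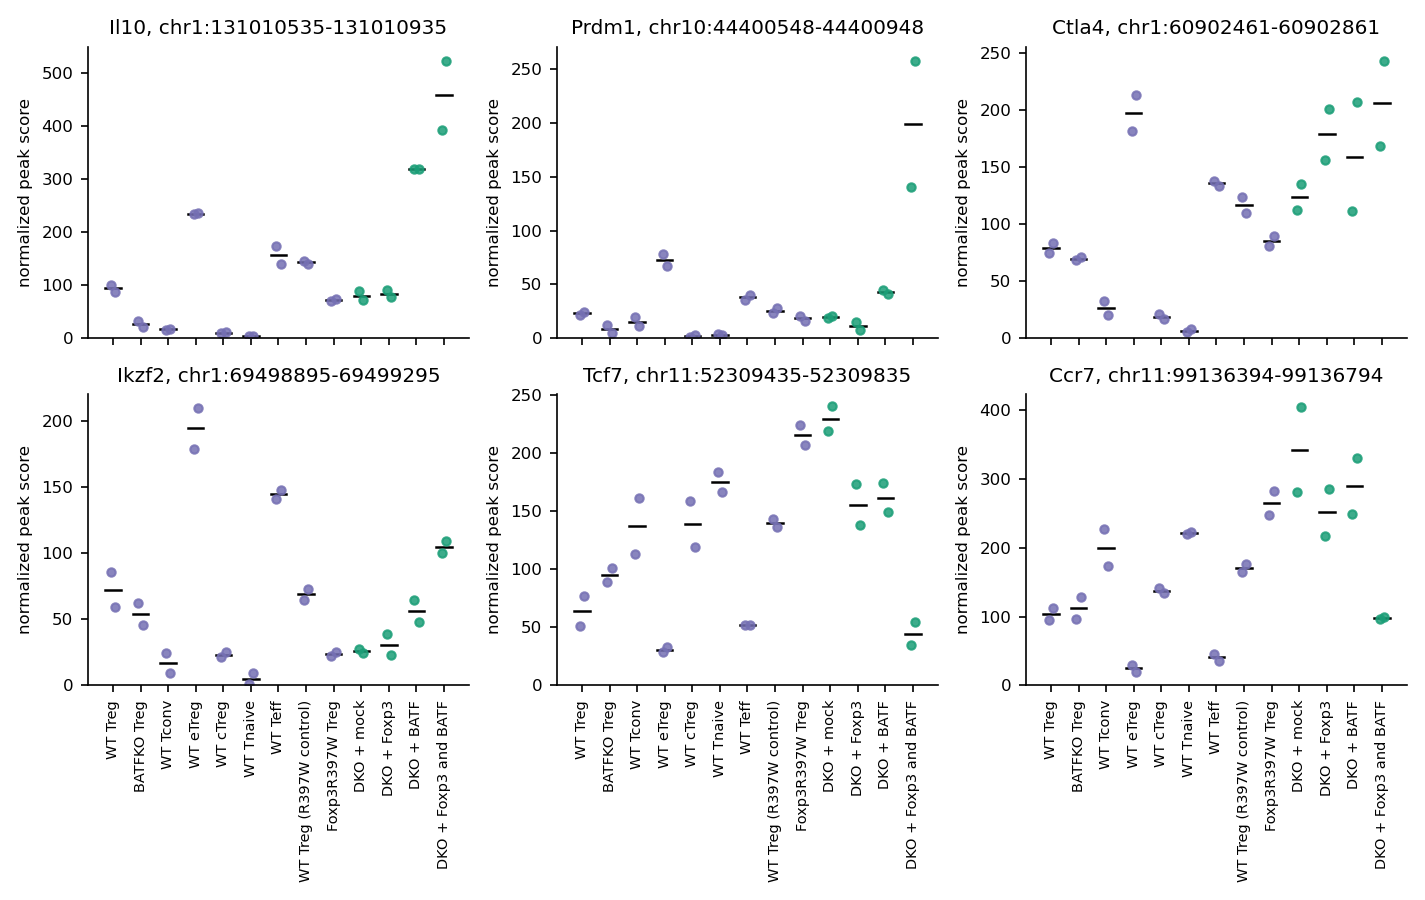
Normalized score of each library at peaks near Il10, Prdm1, Ctla4, Ikzf2, Tcf7 and Ccr7, by group; points are libraries, lines are group means and the axes start at 0. The Il10 peak averages 80.5 with mock virus, 320 with BATF and 459 with both.

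The interaction asked whether both factors together differed from the sum of their separate log2 effects. At a peak 14189 bp from the body of Plg, the plasminogen gene (chromosome 17, 12364020 to 12364420), scores were 548 ± 110 with both, 69.1 ± 6.5 with Foxp3, 127 ± 24 with BATF and 86.4 ± 12 with mock virus (2.41, SE 0.31, adjusted p = 0.00087), and at a peak in Fstl4, a follistatin-like gene, 231 ± 35, 7.52 ± 4.6, 71.9 ± 6.7 and 24.8 ± 2.3 (3.37, SE 0.48, 0.0021). At Enpp1, an ectoenzyme gene, they were 16.8 ± 7.2, 96.3 ± 3.8, 112 ± 6.2 and 121 ± 21 (−2.41, SE 0.35, 0.0021). The naive and central list had 1 higher and 15 lower peaks (4 and 52 adjusted over the list alone, list adjusted p = 2.6e-11, and 0.11 with an estimated correlation), the effector Treg list 3 higher and myeloid markers 2 higher (0.00086 and 0.015, and adjusted p = 0.11 for both with an estimated correlation).

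In all, 406 peaks lay above and 351 below the sum; quantile scaling gave 170 and 242, and TMM 374 and 521, moving the share above from 53.6% to 41.3% and 41.8%. The count of 757 depended on the fit. When only the 4 DKO groups were fitted with limma, 0 peaks passed, Plg, Fstl4 and Enpp1 included (smallest adjusted p 0.078; 6566 at an unadjusted p under 0.05; 487 with edgeR on all groups), and with a replicate block in that fit 2589 passed, 1458 above and 1131 below. It was 12 against a 1.5-fold change, 60 within 1 protocol, 1519 with pseudocount 5, 465 with the low filter, 1762 with a replicate block on all groups and 171 of 45209 peaks with at least 10 reads in each DKO library (57 above and 114 below the sum; 0.378% of these peaks, against 1.09% of all). It was 186 without BATF 2, 251 without Foxp3 2, 398 without mock 2, 502 without mock 1, 492 without BATF 1 and 1802 without Foxp3 1.

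The sets were also followed across the retroviruses. Peaks higher in eTreg had medians of 0.12 with Foxp3 (325 called higher and 104 lower; adjusted p = 0.00019, and 0.061 with a replicate block and an estimated correlation), 0.29 with BATF (1742 and 21, 4.9e-21) and 0.77 with both (5481 and 337, 9.6e-33), and 0.31 for the interaction (2.3e-07). Peaks lower in eTreg had medians of −0.12 (0.0019, and adjusted p = 0.10 with an estimated correlation), −0.16 (2.5e-06), −0.52 (7.8e-22) and −0.28 (5.2e-11). Of the 989 peaks lower in BATFKO Treg, 732 (74.0%) were higher with BATF (odds ratio 128, 95% interval 110 to 150), 863 (87.3%) with both (51.2, 42.4 to 62.3) and 40 with Foxp3 (4.31, 3.03 to 5.98, all Fisher's exact test). With Foxp3 alone this set had a median of 0.08 (adjusted p = 0.065). Of the 1283 peaks lower in Foxp3R397W Treg, 150 (11.7%) were higher with Foxp3 (16.2, 13.3 to 19.7), 344 with BATF (12.9, 11.3 to 14.8) and 944 (73.6%) with both (21, 18.5 to 23.9). Of the 538 peaks higher in Foxp3R397W Treg, 135 (25.1%) were lower with Foxp3 (53.3, 42.7 to 66.4) and 468 (87.0%) with both (61.1, 47.4 to 80). The retrovirus contrasts share their mock libraries, so they were not tested against one another.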

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

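Of the tests below, those of the Tnaive pair, of the cTreg, eTreg and Teff names, of the share of effector cells, of the authors' scaling and of peaks with few reads were chosen only after the result was seen, and the tests of shifted names and of single libraries before.

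Differences between groups stood out in each interaction. The effector step differed between Treg and conventional T cells at 2708 peaks, the effect of the libraries labelled Foxp3KO differed at 38837 peaks from that of the libraries named Foxp3R397W in the 22-library table (cTreg and eTreg in the other), and both retroviruses together differed from the sum of each at 757 peaks, all in limma's test of the difference itself. Signal also appeared in libraries outside the main comparisons. The Foxp3 peak scored 1060 in the libraries called Tnaive and 714 in those called Teff in the 22-library table, which the 26-library table lacks, against 6.21 ± 3.4 in Tconv of that table. Mean scores over all peaks were also higher in these libraries (307 to 323) than in Tconv (93.8 and 77.6), so the gap is not one of this peak alone.

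The first pattern weighed was the 12 libraries with different names in the 2 tables. If the 22-library names had shifted along its columns, its pair called Teff against its pair called Tnaive would follow the Foxp3R397W effect. Across 66144 peaks that change had r = 0.82 with the Foxp3R397W effect and −0.61 with Teff against Tnaive, a difference of 1.43 (1.17 to 1.43 over single library pairs), so a shift is a candidate explanation. The reverse is that the 26-library table misnames its Tnaive pair and these are WT Treg. Their Treg index lay 4.06 below WT Treg, a difference of −4.06 (−2.93 and −2.90 against 1.16 and 1.41). The pair that the 26-library table calls cTreg also lay below WT Treg (−0.019 and −0.115), so a low index alone cannot decide. The Foxp3 peak of the Tnaive pair, given above under the label WT control of Foxp3KO, lay far below WT Treg, which argues against the reverse. The 22-library names of its cTreg and eTreg pairs are argued against too. Mean log2 scores at naive and central genes minus those at effector Treg genes should be higher in the CCR7-high cTreg than in the CCR7-low eTreg, and were lower by 0.74 (0.42 against 1.16, a difference of −0.74, −0.84 to −0.64 over single library pairs). Under the 26-library names they ran as sorted (1.21 against −0.78, a difference of 1.99, 1.87 to 2.11). The 22-library names Tnaive and Teff, cells sorted as negative for the Foxp3 reporter, are argued against by a Foxp3 peak at least 6.18 log2 above Tconv. Mean scores over all peaks were higher too, though by less (307 to 323 against 93.8 and 77.6 in Tconv). The low Treg index and Foxp3 peak of the pair that the 22-library table names WT control of Foxp3KO also argue against that name. The contrast of the libraries labelled Foxp3KO with that pair is therefore not read as an effect of Foxp3 loss. Beyond that, which libraries are Foxp3R397W, Foxp3KO and their controls stays open, and no biological explanation was tested.

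The second pattern was the lower accessibility of eTreg-higher peaks in BATFKO and Foxp3R397W Treg. A lower share of effector cells among the sorted cells would lower these peaks alike at a matched eTreg change. In BATFKO Treg the peaks that BATF retrovirus opens (1742) fell further than matched others (medians −1.43 and −0.43, difference −1.0, −1.11 to −0.91), and in Foxp3R397W Treg so did the 325 that Foxp3 opens (−1.34 and −0.75, difference −0.60, −0.74 to −0.52), which argues against that share as the whole cause. With quantile scaling the medians were −0.32 and −0.48 (camera p = 1.3e-26 and 6.7e-44), against −0.30 and −0.55, so the authors' scaling was not the whole cause. A loss of BATF or Foxp3 function at these sites may contribute, and a change in which effector cells were sorted stays open.

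The third pattern was the departure from the sum of both factors in DKO Treg. Peaks with few reads were not the whole cause: of 45209 peaks with at least 10 reads in each DKO library, 339 were among the 757 and 171 passed when these peaks were fitted alone (50.4% of that count), 57 above and 114 below the sum against 406 and 351 in the main fit. The called share fell from 1.09% of all peaks to 0.378%, so few-read peaks may still add to the count. A single library was not the cause of every call, as 81 of the 757 peaks (10.7%) were called in the fit of all libraries and in all 8 fits without 1 DKO library. Most calls were lost in at least 1 of these fits. Dependence on a single library and the smaller number of libraries cannot be told apart there, so single libraries may still drive most of the count. Virus dose and expression of the transgenes could also make effects differ from a sum, and were not tested. The effect stays a hypothesis, since its count depended on the fit: with only the 4 DKO groups fitted, 0 peaks passed with limma (6566 at an unadjusted p under 0.05; edgeR on all groups called 487) and 2589 with a replicate block. With all groups fitted the block gave 1762.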

How the results depend on the processing

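The tests with edgeR on recovered reads, with the names or reads of the 22-library table, with a minimum of 10 reads, and with a replicate block where said below were chosen only after the results were seen. Where a value moved, the cause was not tested, except that a 1.5-fold test is stricter by construction.

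Against a 1.5-fold change the counts were 356 for BATFKO, 16498 for the libraries labelled Foxp3KO, 100 for Foxp3R397W, 13436 for eTreg against cTreg, 14987 for Teff against Tnaive, 4497 for cTreg against Tnaive, 4108 for eTreg against Teff, 4811 for Treg against Tconv, 62, 943 and 6768 for Foxp3, BATF and both retroviruses, 745 for the effector interaction and 12 for that of Foxp3 and BATF. Pseudocount 5 gave 1600 for BATFKO, 2786 for Foxp3R397W, 4217 and 1519 for those interactions. Quantile scaling gave 2511 for BATFKO, 324 for Foxp3 retrovirus and 412 for the interaction of Foxp3 and BATF, where the low filter gave 465. With only the compared groups in the fit, Foxp3R397W had 6571, eTreg against Teff 19384, Foxp3 retrovirus 334, the effector interaction 4555 and that of Foxp3 and BATF 0 with limma (smallest adjusted p 0.078; 6566 at an unadjusted p under 0.05; edgeR on all groups 487). Within 1 protocol, as read from the 26-library names, Foxp3 retrovirus had 547 and that interaction 60. All 4 omniATAC WT Treg libraries as control gave 2859 for the libraries labelled Foxp3KO and reversed a peak at Klrd1 (0.027) and one at Itgam (0.083). The added settings gave 1797 (BATFKO), 6303 (Foxp3R397W) and 487 (interaction of Foxp3 and BATF) with edgeR, and 171 with at least 10 reads. The 22-library table gives the names Foxp3R397W and its control, eTreg, cTreg, Teff and Tnaive to other libraries. Under its names the counts were 28328 for Foxp3R397W, 3864 for eTreg against cTreg, 4158 for Teff against Tnaive, 5 for cTreg against Tnaive and 4 for eTreg against Teff. The effector interaction had 0 with limma (465 at an unadjusted p under 0.05, and 2705 with edgeR under the 26-library names). WT Treg, Tconv and BATFKO are named alike in both tables. There Treg against Tconv had 20679 (14827 higher and 5852 lower, against 7012 and 6878) and BATFKO 1418.

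Leaving out 1 library at a time leaves a group with a lone sample that is assumed to vary like the others. The counts ranged from 347 (without WT Treg 1) to 782 for BATFKO (659 without BATFKO 2), 25621 to 29178 for the libraries labelled Foxp3KO, 287 (without control 1) to 495 (without Foxp3R397W 2) for Foxp3R397W (470 without control 2, 455 without Foxp3R397W 1), 19369 to 20088 for eTreg against cTreg, 21367 to 22602 for Teff against Tnaive, 7582 (without cTreg 1) to 8411 for cTreg against Tnaive, 6891 (without Teff 2) to 7859 (without Teff 1) for eTreg against Teff (7621 and 7540 without eTreg 1 and 2), and 8332 (without WT Treg 1) to 10167 for Treg against Tconv. They ranged from 321 (without mock 2) to 1882 (without Foxp3 1) for Foxp3 retrovirus (564 without Foxp3 2), 1460 (without BATF 2) to 2232 for BATF (1463 without mock 2) and 10773 (without mock 2) to 14138 for both. For the effector interaction they ranged from 1347 (without Teff 2) to 2335 (1685 and 1738 without eTreg 1 and 2, 1689 without cTreg 2, 1692 without Teff 1), for the libraries labelled Foxp3KO against Foxp3R397W from 35263 to 36698, and for Foxp3 and BATF from 186 (without BATF 2) to 1802 (without Foxp3 1; 251 without Foxp3 2, 398 and 502 without mock 2 and 1, 492 without BATF 1).

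The titles share no replicate numbers between the groups of the Foxp3KO contrast and of its interaction with Foxp3R397W in the 22-library table. A replicate block on the numbers that the 26-library table gives the same libraries, added after the results were seen, gave 33845 (r = 0.06 between deviations) and 39158 (0.05 to 0.08), against 33719 and 38837. For Foxp3R397W the titles share no number with the control, but the columns of the 26-library table number both pairs 1 and 2 (r = 0.33 between deviations), and a replicate block on these, added after the results were seen, gave 1783. Libraries with the same number had r = 0.16 between WT Treg and BATFKO. A replicate block gave 1069 for BATFKO, 25439 for eTreg against cTreg, 27772 for Teff against Tnaive, 11581 for cTreg against Tnaive, 11841 for eTreg against Teff, 14036 for Treg against Tconv, 1699, 2644 and 17011 for Foxp3, BATF and both retroviruses, 2791 for the effector interaction and 1762 for that of Foxp3 and BATF. In the fit of only the DKO groups that interaction had 2589 with the block, also added after the results were seen. At the preset correlation the block changed no call of the lists or eTreg peak sets in DKO Treg, and with an estimated correlation B cell markers with Foxp3 retrovirus went from 0.04 to 0.056 and eTreg-higher peaks with Foxp3 retrovirus from 0.035 (adjusted over 35 tests) to 0.061 (over 2). Of 132 list tests 50 passed, 25 with an estimated correlation and 40 with peaks within 20 kb. All 12 tests of eTreg peak sets passed with 2-fold sets and with quantile scaling, and 11 with an estimated correlation, the exception being eTreg-lower peaks with Foxp3 retrovirus (−0.12, p = 0.099). All 17 overlaps passed at a stricter adjusted p of 0.01. Of 12466 values of 822 named peaks under other settings, 11671 kept their direction and side of the threshold, 664 fell short of it, 129 newly passed and 2 reversed. The motif alternatives, and all 4 omniATAC WT libraries as control of Foxp3R397W, were not run. On simulated data 56 to 62 of 100 changes of 2-fold passed.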

Other observations

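The peak sets that follow were chosen only after the counts were seen. The Treg index was 1.33 and 1.06 in WT Treg and −2.54 and −2.60 in Tconv. The index also followed the effector state. It was 2.44 and 2.44 in eTreg, −0.24 and −0.33 in cTreg and −0.01 and −0.14 in Teff, so cTreg lay below Teff. It thus does not measure Treg identity alone. It was 0.56 and 0.38 in BATFKO Treg, and −0.22 and −0.33 in Foxp3R397W Treg against 1.21 and 1.13 in their control. In DKO Treg it was −0.12 and −0.33 with mock virus, 0.72 and 0.63 with Foxp3, 0.44 and 0.39 with BATF and 1.70 and 1.77 with both. The 7012 peaks higher in WT Treg than in Tconv had a median change of −0.61 in Foxp3R397W Treg (2 called higher and 918 lower; adjusted p = 4.4e-51), 0.28 with Foxp3 retrovirus (348 and 11; 1.4e-15) and 0.64 with both (2749 and 237; 1.7e-21). The 6878 peaks lower in WT Treg had medians of 0.51 (491 and 4), −0.34 (10 and 358) and −0.72 (204 and 2898).

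With BATF retrovirus in DKO Treg, a peak at Il1rl1, the IL-33 receptor, rose from 3.54 ± 0.53 with mock virus (7 reads) to 52.1 ± 16, and one at Rora from 6.02 ± 2.5 to 53.4 ± 4.9 (3.52 and 3.00; adjusted p = 0.00016 and 6e-06). With both viruses the Rora peak scored 92.5 ± 14 (3.78). Between eTreg and Teff, a peak at Gata3, the type 2 lineage factor, was lower in eTreg (57.2 ± 13 against 267 ± 1.1; −2.22), as was one at Nkg7, a cytotoxic granule gene (24.4 ± 1.5 against 202 ± 28; −2.99). Of 16 peaks at Gata3, 2 were higher and 3 lower in eTreg than in Teff. The 3 peaks on chromosome Y held 0 reads in each of the 18 libraries outside the DKO groups and 429 to 722 reads in each of the 8 DKO libraries.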
